A study of Mus musculus with 6 samples.

How the data were processed

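Ventricular cardiomyocytes of adult mice were isolated by collagenase perfusion of the heart, attached for 2 h in medium with 5% fetal bovine serum and cultured without serum, per the labels' protocols. The medium held 25 uM blebbistatin, a myosin inhibitor that stops contraction. Cells were infected at a multiplicity of infection of 100 with an empty adenovirus or with an adenovirus carrying the cDNA of JP2 or of JP2NT, per the labels' protocols. Total RNA was taken 48 h after infection, treated with DNase and labelled with biotin by a 3' in vitro transcription kit, per the labels' protocols. Each of the 3 groups has 2 arrays titled biological replicate 1 and 2. Nothing in the sources used here says whether separate hearts, isolations or dishes lie behind a number, so p-values measure the spread between these arrays, which may be partly technical.

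The values are log2 intensities per probe set, as deposited by the authors, for 45101 probe sets on each of the 6 arrays. Limma 3.22.7 is named per the submitters' processing notes; the background correction, normalization and summarisation methods are not given in the sources used here. The log2 scale was read from the values themselves, with array medians from 6.18 to 6.28. Array quantiles were close but not identical, and the upper quartile differed by group. It was 8.50 and 8.47 with empty virus, 8.38 and 8.32 with JP2 and 8.27 and 8.24 with JP2NT. An array has no read depth, so the number of arrays limits the precision, and no detection calls were used here. No column of the table was left out.

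Probe sets were named from the platform annotation. Of the 45101 probe sets, 35890 had an annotated gene, 34945 had a single symbol, 932 had several symbols and 9211 had no listed gene. Gene identifiers of 34741 single-symbol probe sets matched a current mouse gene table, and 0 symbols had to be updated. The 64 array control probe sets were left out of the tests. For each of 18193 genes the probe set with the highest mean over the 6 arrays was used; 9010 genes had more than 1 probe set. No filter on dim genes was applied. No genome build is named in the sources used here, so no coordinates are given.

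A linear model with a term for each group was fitted to all 6 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, leaving 3 residual degrees of freedom. The comparisons were JP2NT against empty virus, JP2 against empty virus and JP2NT against JP2. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors from this fit, and group levels are means ± SD. Gene lists, 32 in number with 620 members, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The lists cover calcium handling and the dyad, sarcomere, hypertrophy, MEF2 targets, cardiac transcription factors, intercalated disc, ion channels, adrenergic signaling, metabolism, stress responses, growth signaling, immune responses and markers of fibroblasts, endothelium, smooth muscle, leukocytes and erythroid cells. Member counts adjusted over the list alone are given beside those over all genes. The tests, lists and rules were fixed before the data were examined.

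The genes named follow a rule. It takes Jph1 to Jph4 in every comparison. It takes per direction the 10 called genes with the largest change and no overlap between the arrays of both groups, filled to 5 by the smallest unadjusted p where fewer than 5 pass. Clone names and accessions are passed over. Per list it takes up to 4 called members with the largest change, or where none passes the 2 members with the smallest unadjusted p. It adds a fixed set in every comparison, namely Nppa, Nppb, Myh6, Myh7, Acta1, Ryr2, Atp2a2, Cacna1c, Mef2c and Col1a1. The report names a part of these genes.

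The replicate numbers are shared between the groups, and they marked a difference between the arrays. After subtracting group means, the deviations of arrays with the same number correlated across genes at 0.52, 0.57 and 0.50 for the pairs of groups, and 3 of the 6 arrays correlated best with an array of their own number. Spiked controls also differed between the numbers. A fit with the number as a block was planned as an alternative and leaves 2 residual degrees of freedom. Its p-values stand beside the named results whose call it changes, and changes within each number beside the lists called and some genes. The number was treated as a batch of unknown origin.

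The alternatives named before the data were seen were the mean of all probe sets of a gene, leaving out the dimmest 40% of genes, quantile normalization, centring each array on its median, a variance trend with robust estimation, a fit on only the arrays of both groups compared, the replicate block, all probe sets in place of genes, camera with an estimated correlation, the set test fry, separate empty virus arrays for the correlation of effects, and leaving out each array in turn. The block combined with quantile normalization or with the estimated correlation was added after seeing the data. A count of how often other splits of the arrays give as many calls does not apply to groups of 2. The steps were tested on simulated data with 200 changed genes among 18193. The simulated arrays held an additive replicate number difference and spreads, both taken from the fit with the block. They therefore favour that fit, and its share of false calls in the real arrays was not tested. In JP2NT against empty virus the fit without the block recovered 3% of simulated 2-fold changes and 79.6% of 4-fold changes, with 0.242% false calls, and the fit with the block recovered 54.2% and 98.4% with 4.39% false calls. In JP2 against empty virus these shares were 1.6% and 76.2% without the block and 53.4% and 99% with it. In JP2NT against JP2 they were 1.4% and 76.6% without the block and 50.4% and 98.2% with it.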

Results

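Gene expression was measured on Affymetrix 3' arrays in cultured ventricular cardiomyocytes of adult mice, 48 h after infection with an empty adenovirus, with a virus carrying JP2 or with a virus carrying JP2NT. JP2 is junctophilin-2, the product of Jph2, which tethers the plasma membrane to the sarcoplasmic reticulum at the cardiac dyad; JP2NT is known from earlier work as an N-terminal fragment of that protein. The empty virus served as the control for infection itself. Each group had 2 arrays, 6 in all. The first principal component held 46.7% of the variance over genes and the second 27.5%. On the first, JP2NT replicate 2 scored 53.6 and JP2NT replicate 1 29.9, while the other 4 arrays scored -26.2 to -18.2. The difference between 3' and 5' actin control probe sets, a sign of RNA quality, was smallest with JP2NT. It was 0.69 and 0.78 log2 units in replicates 1 and 2, against 0.94 and 1.27 with empty virus and 0.87 and 1.12 with JP2. For GAPDH it was 0.20 and -0.086 with JP2NT, 0.23 and -0.0061 with empty virus and 0.17 and 0.0076 with JP2. The arrays of a group correlated with each other at 0.988 for empty virus, 0.986 for JP2NT and 0.985 for JP2, while the replicate 1 arrays of empty virus and JP2 correlated at 0.995. Spiked hybridization controls were 1.35 log2 units higher on replicate 2 than on replicate 1 arrays, in every group by 1.23 to 1.49, although the median of all genes differed by 0.02. Markers of other cell types also differed between the replicate numbers: the median of endothelial markers was 0.86 and of fibroblast markers 0.56 log2 units higher in replicate 2 (adjusted p = 2.78e-08 and 5.29e-08, and adjusted p = 0.478 for each with an estimated correlation). The interferon response differed by more, with a median 1.13 log2 units higher in replicate 2 (camera adjusted p = 7.21e-17, and 0.478 with an estimated correlation). Medians of the lists within each replicate number are therefore given beside pooled ones for the lists called and the markers, with the values of some genes.

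**Figure D1:**
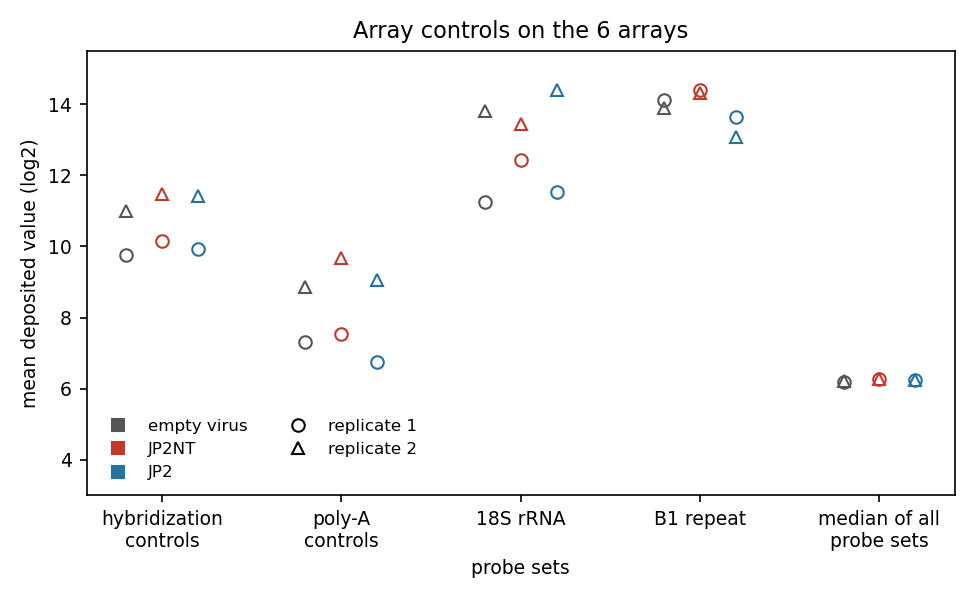
Mean deposited log2 value (vertical axis) of array control probe sets and the median of all probe sets on each of the 6 arrays, coloured by group, with circles for replicate 1 and triangles for replicate 2. Spiked hybridization controls lay 1.35 log2 units higher on replicate 2 arrays on average, while the array medians stayed between 6.18 and 6.28.

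The delivered gene was read first. Jph2 has 2 probe sets on the array. On the dimmer of them the level was 8.34 ± 0.14 with empty virus, 9.12 ± 0.30 with JP2NT and 10.18 ± 0.02 with JP2 (log2, mean ± SD, n = 2 each). JP2 arrays were thus 3.57-fold above empty virus (1.84 log2 units, SE 0.19) and JP2NT arrays 1.71-fold above it (0.78, SE 0.19). Over all probe sets these differences missed the threshold (adjusted p = 0.618 for JP2 and 0.0955 for JP2NT), and with the replicate number as a block they had adjusted p = 0.113 and 0.0322; adjusted over the list alone, the 7 junctophilin probe sets, they had adjusted p = 0.000461 and 0.0215. The brighter Jph2 probe set averaged 11.18 with empty virus, 11.22 with JP2NT and 11.00 with JP2. Its values parted by replicate number, with 11.84 and 10.52 for replicates 1 and 2 of empty virus, 11.70 and 10.74 of JP2NT and 11.60 and 10.41 of JP2. Where either probe set lies relative to the delivered cDNA was not established. Jph1, the skeletal muscle junctophilin, differed by -0.94 log2 units with JP2NT (SE 0.23, adjusted p = 0.0811 over all genes, 0.0142 with the block). Its dimmer probe set differed by only -0.12 (adjusted p = 0.743 over all probe sets, 0.633 with the block). Jph3 differed by 0.37 and Jph4 by 0.44 log2 units with JP2NT, neither past the test.

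**Figure D2:**
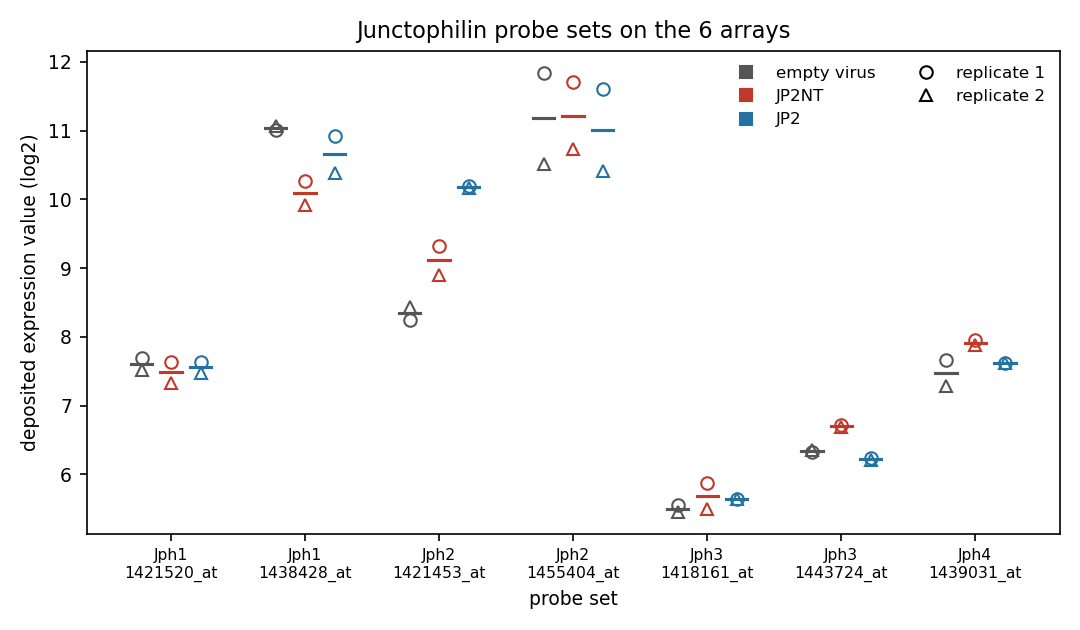
Deposited log2 values (vertical axis) of the 7 junctophilin probe sets on the 6 arrays, with bars for the group means and circles and triangles for replicates 1 and 2. On the dimmer Jph2 probe set the groups stood at 8.34 (empty virus), 9.12 (JP2NT) and 10.18 (JP2), whereas the brighter one parted the replicate numbers rather than the groups.

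JP2NT against empty virus asked what the fragment changes in the cardiomyocyte transcriptome. Ptgs2, the inducible cyclooxygenase, fell from 9.96 ± 1.54 to 5.24 ± 0.27 (log2, mean ± SD, n = 2 each; change -4.72, SE 0.65, adjusted p = 0.0329). Its level with JP2NT lay near the lower quartile of those arrays (4.97 and 4.98), where signal over background was not tested, so the size of the fall is uncertain. Its other probe set differed by -1.78. The developmental transcription factor Sox4 fell by a factor of 7.47 (change -2.90, SE 0.19, adjusted p = 0.0257), and the flow- and MEF2-responsive factor Klf2 by a factor of 6.36 (change -2.67, SE 0.26, adjusted p = 0.0259). Nppb, which encodes the natriuretic peptide BNP, fell by a factor of 4.01, from 12.94 ± 0.08 to 10.94 ± 0.23 (change -2.01, SE 0.17, adjusted p = 0.0257). The genes that rose did so by smaller factors, led by the complement-related pseudogene C4bp-ps1 (3.60-fold, SE 0.29 on the log2 scale, adjusted p = 0.0392), the hydrolase gene Cmbl (2.97-fold) and the properdin gene Cfp (2.95-fold).

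Among the other large falls were Tox3 (-3.00), the deubiquitinase gene Otud1 (-2.75), Star, which carries cholesterol into mitochondria (-2.70), the hyaluronan receptor Cd44 (-2.70), Ndnf (-2.59), the corepressor gene Lcor (-2.58) and Zfp697 (-2.49 on the log2 scale). Other genes that rose included Fitm1, a lipid droplet protein (1.47), the glutathione transferases Gstm7 (1.47) and Gstt1 (1.33), Spata33 (1.42), the elongation factor Tcea3 (1.39), Aspm (1.32) and the methionine sulfoxide reductase Msrb2 (1.29). Sizes differed between the replicate numbers. Ptgs2 differed by -3.82 in replicate 1 and by -5.62 in replicate 2, Star by -1.94 and -3.46, Sox4 by -2.69 and -3.11, Fitm1 by 0.92 and 2.02, and Cfp by 1.45 and 1.67. Some of them have probe sets that disagree: the 8 probe sets of Sox4 ranged from -2.90 to 0.058 and the 4 of Cd44 from -2.70 to 0.13. Those of Ndnf, Lcor, Gstm7 and Aspm kept 1 sign but reached down to -0.28, -0.030, 0.088 and 0.047.

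**Figure D3:**
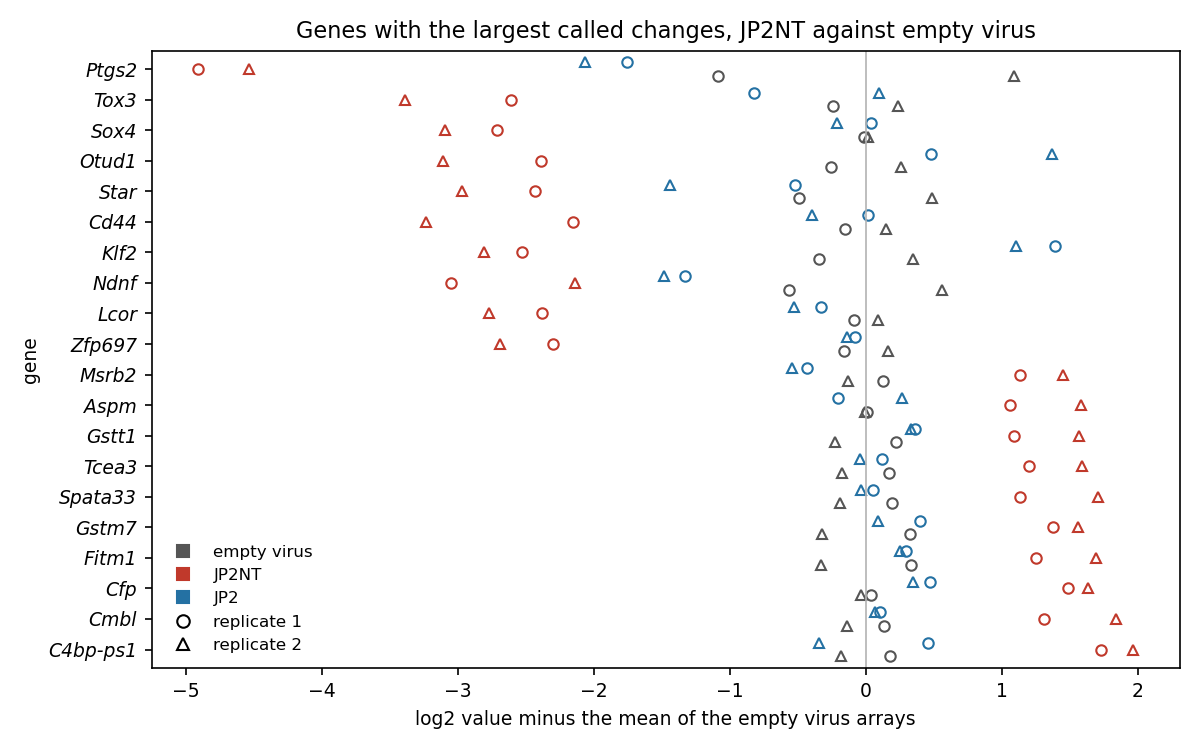
Log2 value of each array minus the mean of the empty virus arrays (horizontal axis) for the 10 genes that fell the most and the 10 that rose the most in JP2NT against empty virus, coloured by group, with circles for replicate 1 and triangles for replicate 2. The genes were picked for no overlap between JP2NT and empty virus arrays, so their separation follows from the choice. Mean changes ran from -4.72 for Ptgs2 to 1.85 for C4bp-ps1.

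In all, 548 of 18193 genes passed the test, 39 higher and 509 lower, so that 92.9% were lower, and 460 of the 548 changed more than 2-fold. At an unadjusted p under 0.05 there were 4046 genes. With the replicate number as a block 2940 genes passed, 815 higher and 2125 lower, among them all 548. After quantile normalization 72 passed (6 higher, 66 lower), and with both the block and quantile normalization 2764 passed (1229 higher and 1535 lower, so that 55.5% were lower). Leaving out any single array left 0 to 255: 1 without empty virus replicate 1, 0 without empty virus replicate 2 or either JP2NT array, and 255 without either JP2 array. Of the 548 genes 365 had several probe sets, of which 165 had at least 1 probe set of opposite sign and 26 an opposite probe set at an unadjusted p under 0.05.

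Of the 32 gene lists 8 were called, 4 higher and 4 lower. Immediate early and ERK feedback genes, which report growth factor and MAP kinase signaling, fell as a list (median -0.79, -0.78 in replicate 1 and -0.76 in replicate 2, adjusted p = 0.000101, and adjusted p = 0.781 with an estimated correlation). Of their 23 members 5 fell and 0 rose over all genes, and 8 fell and 1 rose when adjusted over the list alone. These included Myc (-1.87, from 11.46 ± 0.14 to 9.59 ± 0.08, n = 2 each), Phlda1 (-1.81), the MAP kinase phosphatase Dusp1 (-1.79) and the ERK inhibitor Spry2 (-1.79). Cardiac transcription factors fell as well (median -0.71, -0.64 and -0.91 in replicates 1 and 2, adjusted p = 0.00541, and adjusted p = 0.781 with an estimated correlation). Of 20 members 3 fell, the heart development factors Hand2 (-2.09) and Gata6 (-1.40) and the mitochondrial coactivator Ppargc1b (-1.52); adjusted over the list alone, 8 fell and 1 rose. Probe sets of Hand2 disagreed in sign, from -2.09 to 0.16. Heat shock genes fell as a list (median -0.36, -0.16 and -0.48 in replicates 1 and 2, adjusted p = 0.016, and adjusted p = 0.781 with an estimated correlation), with 0 of 14 members past the test over all genes or adjusted over the list alone; Hsph1 differed by -0.47 and Chordc1 by -0.38. NRF2 targets fell (median -0.25, -0.15 and -0.34, adjusted p = 0.0478, and adjusted p = 0.781 with an estimated correlation), with 2 of 16 members past the test and 3 adjusted over the list alone. Both are inducible by stresses other than NRF2 activation, namely the cystine transporter Slc7a11 (-1.89) and the metallothionein Mt2, which fell 2.0-fold.

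Genes of mitochondrial energy metabolism were higher with JP2NT as lists, although 0 of their members passed the test singly without the replicate block. Fatty acid oxidation rose (median 0.51, 0.30 in replicate 1 and 0.73 in replicate 2, adjusted p = 0.000101, and adjusted p = 0.781 with an estimated correlation). Of its 20 members 5 rose when adjusted over the list alone; the carnitine-acylcarnitine carrier Slc25a20 differed by 0.98 (adjusted p = 0.0553, 0.0148 with the block) and Eci1 by 0.68 (adjusted p = 0.0629, 0.0237 with the block). With the block 6 of the 20 rose over all genes. Oxidative phosphorylation rose over 24 members (median 0.24, 0.13 and 0.35, adjusted p = 0.00541, and adjusted p = 0.781 with an estimated correlation), with Ndufs1 at 0.33 and Ndufa9 at 0.32, and the TCA cycle and pyruvate dehydrogenase rose over 15 (median 0.23, 0.16 and 0.33, adjusted p = 0.026, and adjusted p = 0.781 with an estimated correlation), with Suclg1 at 0.51 and Dlat at 0.47; adjusted over the list alone, 0 members of either passed. MHC class I antigen presentation rose over 11 members (median 0.30, 0.33 and 0.37, adjusted p = 0.0226, and adjusted p = 0.781 with an estimated correlation), with 0 members past the test over all genes or over the list alone. With the block 4 rose, among them the proteasome activator Psme1 (0.73, adjusted p = 0.0741, 0.027 with the block) and Psmb10 (0.72, adjusted p = 0.103, 0.0275 with the block). Leaving out empty virus replicate 2 ended the calls of oxidative phosphorylation (adjusted p = 0.0981), the TCA cycle (0.169), MHC class I (0.0545) and heat shock (0.0755). Leaving out empty virus replicate 1 ended those of cardiac transcription factors (0.0987) and NRF2 targets (0.0721), and leaving out JP2NT replicate 2 also that of NRF2 targets (0.109). Leaving out dim genes ended the calls of cardiac transcription factors (0.0783), heat shock (0.133) and NRF2 targets (0.244). Quantile normalization ended that of the TCA cycle (0.0549), and the mean of probe sets that of NRF2 targets (0.0505).

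Members of the hypertrophy and fetal gene list moved both ways. Acta1, the skeletal actin of the fetal heart program, rose 1.91-fold (0.94, SE 0.15, adjusted p = 0.041) while Nppb and Myc of the same list fell, and the hypertrophy list as a whole was not called (median 0.19, mean -0.10, tested higher, adjusted p = 0.789). Over the list alone 3 of its 17 members rose and 3 fell. Nppa differed by 0.75 (adjusted p = 0.358, 0.025 with the block), Myh7 by 0.62 (0.0938, 0.0332 with the block), Myh6 by 0.37 (0.26), Ryr2, the calcium release channel, by 0.92 (0.0599, 0.0158 with the block), Atp2a2 by 0.15 (0.557), Cacna1c by 0.37 (0.388), Mef2c by -0.11 (0.814) and Col1a1 by 0.38 (0.539). MEF2 target genes were not called (median 0.17, mean -0.20, tested lower, adjusted p = 0.789), with 3 of 24 members lower over all genes, Klf2, Klf6 (-2.42) and Hdac9 (-2.10, with probe sets that disagreed in sign), and 4 lower and 1 higher over the list alone. Sarcomere genes had a median of 0.21 (adjusted p = 0.0636, 0.02 with the block, and 0.647 with the block and an estimated correlation). Of 20 sarcomere genes 19 had a positive change, while the thin-filament protein Lmod2 fell (-0.96). Calcium handling had a median of 0.15 (adjusted p = 0.147), with 17 of 23 members positive. After quantile normalization its median was 0.31 (adjusted p = 0.0656, and 0.0384 with the block as well). With the block and an estimated correlation it had adjusted p = 0.647.

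Markers of other cell types stood higher with JP2NT without passing the test, and passed it with the replicate block at the preset correlation. With the block and an estimated correlation each had adjusted p = 0.647. Medians were 0.38 for fibroblast markers (adjusted p = 0.0636, 0.00025 with the block), 0.46 for endothelial markers (0.0811, 0.00427), 0.48 for macrophage and leukocyte markers (0.0636, 0.0115) and 0.38 for smooth muscle markers (0.0676, 0.00912), while the macrophage receptor Csf1r went the other way (-2.03, adjusted p = 0.0825, 0.00254 with the block). Interferon response (0.52, adjusted p = 0.134, 0.00241 with the block) and extracellular matrix (0.34, adjusted p = 0.47, 0.0132 with the block) showed the same, and erythroid markers had 0.33 (0.127). Within replicate numbers these medians were 0.12 and 0.82 for endothelial markers, 0.26 and 0.75 for fibroblast markers, 0.24 and 0.50 for macrophage and leukocyte markers, 0.16 and 0.63 for smooth muscle markers, 0.15 and 0.58 for extracellular matrix, and 0.19 and 0.80 for interferon response. With the block 15 lists were called, 11 higher and 4 lower. With the block and an estimated correlation 0 were called, the matrix and interferon lists also standing at adjusted p = 0.647.

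The other lists were not called. Medians were -0.15 for the unfolded protein response (adjusted p = 0.0811), although its members Chac1 (-2.20) and Trib3 (-1.58), both stress-induced, fell. They were -0.30 for TGF-beta targets (0.0811), -0.38 for adrenergic signaling (0.127), where Rgs2, an inhibitor of Gq signaling, fell by 2.16, and -0.16 for the cell cycle (0.219). NF-kB targets had a median of 0.10 but a mean of -0.39 and tested lower (0.437), and ion channels had 0.30 (0.437), with the gap junction gene Gja1 lower (-1.48). Autophagy and atrophy genes had -0.06 (0.47), p53 targets -0.06 (0.665) with Sesn1 lower (-1.37, with probe sets that disagreed in sign), cytosolic ribosomal proteins -0.03 (0.665) and glycolysis -0.06 (0.67). The intercalated disc had a median of 0.09 and a mean of -0.06 and tested lower (0.675), and cholesterol synthesis had 0.01 (0.807). Dedifferentiation genes had a median of 0.39 and tested lower (0.801), with Acta1 higher and Nes, an intermediate filament gene, lower (-0.82).

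**Figure D4:**
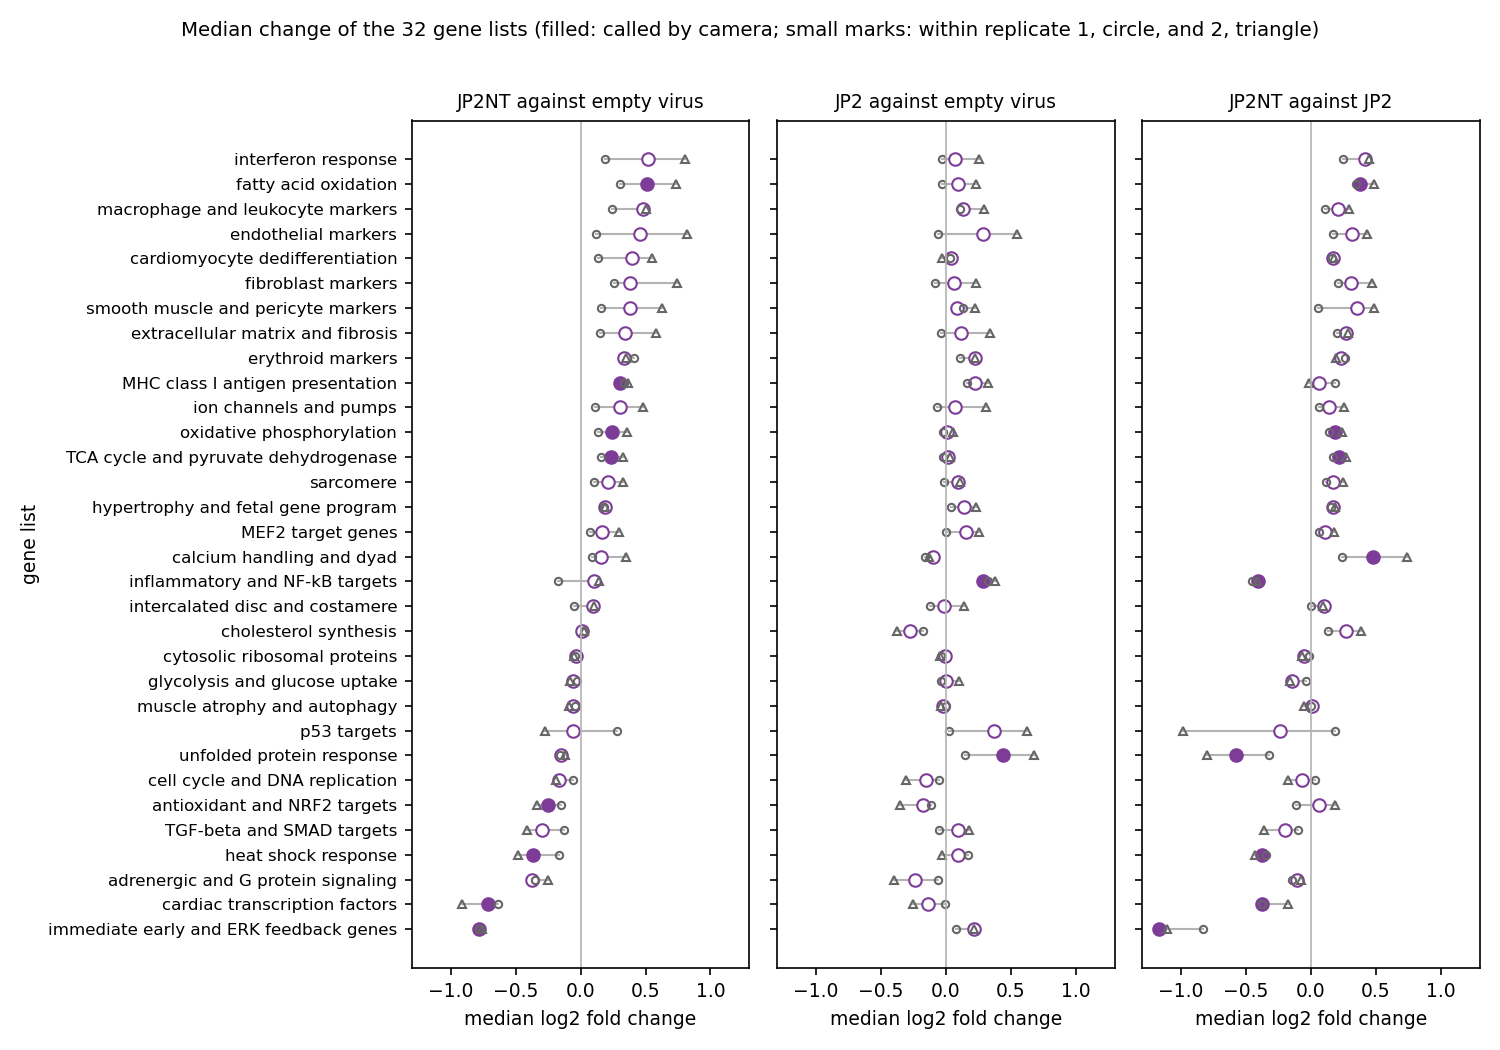
Median log2 fold change (horizontal axis) of the 32 gene lists in the 3 comparisons. Filled circles mark lists called by camera and open ones the others, with small circles and triangles for the medians within replicates 1 and 2; immediate early and ERK feedback genes lie at -0.79 and -1.17 in the JP2NT comparisons.

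JP2 against empty virus asked what the full-length protein changes. Genes that fold and quality-control proteins in the endoplasmic reticulum were higher as a list: the unfolded protein response rose (median 0.44, 0.15 in replicate 1 and 0.68 in replicate 2, adjusted p = 0.000954, and adjusted p = 0.865 with an estimated correlation). Its members included the chaperone Hspa5 at 0.51 and Dnajb9 at 0.57, and 0 of 20 passed the test over all genes or adjusted over the list alone. Inflammatory and NF-kB targets rose (median 0.29, 0.32 and 0.38 in replicates 1 and 2, adjusted p = 0.0406, and adjusted p = 0.865 with an estimated correlation), with Nfkbia, the NF-kB inhibitor, at 1.37 and Relb at 1.17; 0 of 20 members passed over all genes and 1 rose when adjusted over the list alone. The other 30 lists had adjusted p from 0.199 to 0.81.

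No gene was called with limma, where 1591 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.557. With the replicate block 0 genes passed as well, with 2946 at an unadjusted p under 0.05 and a smallest adjusted p of 0.123. The genes with the smallest p therefore stand as values. On the higher side they were the chemokine Cxcl10 (1.73, from 7.99 ± 0.05 to 9.72 ± 0.45, n = 2 each), the clock repressor Nr1d1 (1.98, with 1.44 and 2.52 in replicates 1 and 2), the orphan receptor Nr4a1 (1.20), Gse1 (1.20) and Tubb3 (0.79), and on the lower side Gcnt1 (-1.98), Gnpda2 (-1.63), Ifit1bl1 (-1.36), Armh4 (-1.06) and Pgbd5 (-1.03). The inducible heat shock gene Hspa1b differed by 2.75 (SE 0.71), by 3.72 and 1.78 in replicates 1 and 2 and by 1.60 without empty virus replicate 1. Hspa1a differed by 2.71 (3.79 and 1.63, with empty virus arrays at 8.72 and 11.36), Nppb by -0.87 and Mef2c by -0.79, each of these 4 with adjusted p = 0.557. Leaving out JP2 replicate 2 ended the call of the unfolded protein response (adjusted p = 0.11), and leaving out empty virus replicate 1 (0.206) or centring each array on its median (0.0757) ended that of NF-kB targets.

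JP2NT against JP2 compared the fragment with the full-length protein directly. Lower and higher are meant relative to JP2 here, and a change with either virus can give such a difference. Klf2 fell from 10.34 ± 0.20 to 6.43 ± 0.20 (log2, mean ± SD, n = 2 each; change -3.91, SE 0.26, adjusted p = 0.0235), and Otud1 fell by a factor of 12.8, the small GTPase gene Rhob 7.95, Sox4 7.02, Myc 6.72 and Nfkbia 5.56. Also lower were the ubiquitin ligase of endoplasmic reticulum quality control Syvn1 (-2.71), Tox3 (-2.64), the actin- and SRF-signaling protein Abra (-2.51) and Cd44 (-2.50). Higher with JP2NT were Smr2 (4.29-fold), Msrb2 (3.43-fold), the proteasome subunit Psmb3 (2.95-fold), the ceramidase Asah2 (2.86-fold), Cmbl (2.80-fold), Ifit1bl1 (2.77-fold), the dUTPase Dut (2.73-fold), Tmem14a (2.68-fold), Dppa5a (2.62-fold) and Tmem218 (2.59-fold). Probe sets of Sox4 and Cd44 disagreed in sign, and those of Smr2, Asah2 and Psmb3 reached down to 0.085, 0.027 and 0.23.

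Of the 32 lists 9 were called, 4 higher and 5 lower. Immediate early and ERK feedback genes fell (median -1.17, -0.83 and -1.11 in replicates 1 and 2, adjusted p = 1.23e-06, and adjusted p = 0.719 with an estimated correlation), with 3 of 23 members lower over all genes, Myc, Junb (-2.18) and Phlda1 (-1.84), and 12 adjusted over the list alone. The unfolded protein response fell (median -0.58, -0.32 and -0.80, adjusted p = 2.73e-05, and adjusted p = 0.874 with an estimated correlation), with Chac1 (-2.17) and Trib3 (-2.09) lower over all genes and 7 of 20 adjusted over the list alone. Heat shock genes fell (median -0.38, -0.35 and -0.43, adjusted p = 0.000747, and adjusted p = 0.874 with an estimated correlation), with 0 of 14 past the test over all genes and 2 over the list alone; Hspa1b differed by -4.12 (17.4-fold, SE 0.71, adjusted p = 0.0584, 0.00329 with the block) and Hspa1a by -4.26 (adjusted p = 0.0657, 0.00414 with the block). NF-kB targets fell (median -0.41, -0.45 and -0.41, adjusted p = 0.00339, and adjusted p = 0.719 with an estimated correlation). Of 20 members 1 was lower over all genes, Nfkbia, and 4 over the list alone. Against empty virus this list had a median of 0.10 and a mean of -0.39 with JP2NT, not called. With JP2 it had 0.29 and 0.42, called. The unfolded protein response had -0.15 and -0.30 with JP2NT, not called, and 0.44 and 0.38 with JP2, called. These falls thus include a rise with JP2. Cardiac transcription factors fell (median -0.38, -0.38 and -0.18, adjusted p = 0.0316, and adjusted p = 0.874 with an estimated correlation), with Gata6 (-1.77) the single member of 20 past the test, over all genes and over the list alone.

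Higher with JP2NT than with JP2 were fatty acid oxidation (median 0.38, 0.35 and 0.48 in replicates 1 and 2, adjusted p = 0.000747, and adjusted p = 0.874 with an estimated correlation), with Slc25a20 at 0.98 (adjusted p = 0.0181 with the block) and Eci1 at 0.58 (0.0425 with the block), oxidative phosphorylation (median 0.19, 0.14 and 0.24, adjusted p = 0.00339, and adjusted p = 0.874 with an estimated correlation), with Sdhd at 0.66 (0.0331 with the block), and the TCA cycle (median 0.22, 0.17 and 0.27, adjusted p = 0.0316, and adjusted p = 0.874 with an estimated correlation), with Dlat at 0.56. Calcium handling and dyad genes were also higher (median 0.48, 0.24 and 0.74, adjusted p = 0.00339, and adjusted p = 0.874 with an estimated correlation), with the calcium release partners Trdn at 0.65 (0.0475 with the block) and Tmem38a at 0.72. Against empty virus the calcium handling list had a median of 0.15 and a mean of 0.19 with JP2NT. With JP2 it had -0.10 and -0.19, and neither was called (camera adjusted p = 0.147 and 0.223). The difference thus includes a lower level with JP2. In these 4 lists 0 members passed over all genes without the block. Adjusted over the list alone, 1 fatty acid oxidation gene rose. Random lists of genes of like level had medians of 0.099 for oxidative phosphorylation and 0.10 for the TCA cycle. The observed medians lay at percentiles 87.6 and 87.0 of 10000 such lists, so they were not clearly beyond genes of like level. Fatty acid oxidation lay at percentile 99.95 and calcium handling at 100. Nppb was lower by 1.13 (2.20-fold, adjusted p = 0.046), and of other list members Klf6 (-2.46), Nr4a1 (-1.60), Cxcl10 (-1.97), Mt2 (-1.34) and Lmod2 (-1.26) were lower. Cxcl10 arrays read 7.95 and 8.03 with empty virus, 7.58 and 7.93 with JP2NT and 9.40 and 10.04 with JP2. Its difference thus includes a rise with JP2, while Klf6 with JP2 (11.25 and 11.03) lay near empty virus (11.14 and 11.06). Leaving out JP2 replicate 2 ended the calls of calcium handling (adjusted p = 0.127) and the TCA cycle (0.116), JP2NT replicate 1 those of NF-kB targets (0.0582) and the TCA cycle (0.0639), and JP2 replicate 1 (0.587) or JP2NT replicate 2 (0.121) that of cardiac transcription factors. Quantile normalization ended those of oxidative phosphorylation (0.056), the TCA cycle (0.184) and cardiac transcription factors (0.056). Leaving out dim genes ended those of the TCA cycle (0.0572) and cardiac transcription factors (0.121). Markers of other cell types stood higher here too, with medians of 0.31 for fibroblast markers (adjusted p = 0.165, 0.00113 with the block), 0.36 for smooth muscle markers (0.165, 0.0454), 0.31 for endothelial markers (0.382, 0.0593) and 0.21 for macrophage and leukocyte markers (0.391, 0.252). Interferon response had 0.42 (0.382, 0.00389). With the block and an estimated correlation each of these had adjusted p = 0.773.

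In this comparison 237 genes passed the test, 27 higher and 210 lower, with 228 past 2-fold and 3547 at an unadjusted p under 0.05. With the block 2547 passed, 1011 higher and 1536 lower, among them all 237, and 14 lists were called, 8 higher and 6 lower, or 0 with the block and an estimated correlation. Among those 14 were cholesterol synthesis (median 0.27, 0.13 and 0.38 in replicates 1 and 2, adjusted p = 0.0561, 0.00679 with the block and 0.0178 with quantile normalization) and TGF-beta targets (median -0.20, -0.10 and -0.36, adjusted p = 0.0561, 0.0417 with the block), both at adjusted p = 0.773 with the block and an estimated correlation. With the block and quantile normalization 2427 genes passed, 1133 higher and 1294 lower, or 53.3% lower. Quantile normalization left 128 genes and a fit on only the arrays of both groups 0; without JP2 replicate 1 there were 65, and without any other single array 0. Of the 237 genes 136 had several probe sets, of which 45 had at least 1 of opposite sign.

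The genes lower with JP2NT overlapped between its comparisons: of 509 lower against empty virus and 210 lower against JP2, 174 were shared, and of 39 and 27 higher genes 10 were shared. Independent lists would share 5.88 and 0.0579, but both comparisons use the same JP2NT arrays. Over 100 simulations of unchanged groups, as many genes of lowest p on each side shared 75.3 on average (at most 92) on the lower side. On the higher side they shared 5.99 (at most 11), so the 10 higher genes were not above what the shared arrays give. The calls shared in those simulations averaged 0.010 on each side. With the replicate block 1161 genes were shared of 2125 and 1536 lower ones, and 455 of 815 and 1011 higher ones. No simulated value was made for the overlap with the block. Across all genes the changes with JP2NT and with JP2, each against empty virus, correlated at 0.391 (0.417 and 0.387 within replicates 1 and 2). Genes are not independent replicates, and 2 unchanged groups against shared controls gave 0.50 over 100 simulations. Sharing a control gives that value whatever the spread, and changes of a single group lower the observed correlation. The correlation therefore cannot decide whether JP2NT and JP2 share changes. The covariance was 0.0634 against 0.0300 simulated, a difference of 0.0334. With the spread of the fit with the replicate block the simulated covariance was 0.0154 and the difference 0.0480. With a separate empty virus array for each comparison the correlation was 0.15 or 0.0814. The difference between replicate numbers then enters both changes with opposite sign.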

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

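Of the tests in this part, that of dim genes in the marker pattern was chosen only after the result was seen.

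The spiked hybridization controls, which are added in fixed amounts and enter no comparison of genes, were 1.35 log2 units higher on replicate 2 than on replicate 1 arrays. The poly-A controls, added before labelling, were higher by 2.00 and the 18S ribosomal probe sets by 2.14; these differences stand out because they appear in probe sets outside the measured genes and in each of the 3 groups. A first explanation is less labelled sample against a fixed spike: it needs the 4 hybridization transcripts to move alike, but their mean changes spanned 1.10 log2 units (0.75 to 1.84), and within groups the span went from 0.84 to 1.29, so it cannot be told apart from a nonlinear response to the amount. Separate cell preparations may also lie behind the numbers, since a list of markers of other cell types differed between them by a median of up to 0.86 (smallest adjusted p = 2.78e-08, 4 of 5 lists called, adjusted p = 0.478 with an estimated correlation). Lists other than cell markers differed as well. The interferon response had the largest median, 1.13 (camera adjusted p = 7.21e-17, and 0.478 with an estimated correlation). Between the numbers 1181 of 18193 genes were called, 630 higher and 551 lower in replicate 2. The difference was thus not confined to markers of other cell types. Beyond the share of other cell types, no biological explanation was tested, because the labels do not say what a number marks.

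The genes called in JP2NT against empty virus lean to the lower side (509 of 548). The lean among called genes nearly ends with the replicate block and quantile normalization together (1535 of 2764 lower, 55.5%), where smaller changes are called as well. An additive batch that goes with the number cancels from these changes, because each group has an array of each number. The test within the numbers therefore asked only whether the lean lay in a single number. Among genes past 1 log2 unit, 95.1% were lower within replicate 1 and 72.7% within replicate 2. Both were above the bound of 65% set, so the lean lay in both numbers. Intensity-dependent normalization stays open, since against genes of like level 75.9% of those past 1 log2 unit were lower (91.2% and 63.7% within replicates 1 and 2, under the bound of 65% set for both). The median change of all genes went with their level. It was 0.16 in decile 4 of level, -0.24, -0.23 and -0.11 in deciles 7, 8 and 9, and 0.040 in decile 10. Deciles 7, 8 and 9 held 120, 123 and 92 of the lower calls. After quantile normalization their medians were 0.028, 0.014 and 0.011. As a biological candidate explanation, genes of DNA-binding regulators could have fallen more than other genes; 355 such genes outside the fixed lists and the Zfp family had a level-adjusted median of -0.074 (percentile 0.01 of 10000 matched lists), between the bounds set in advance, so this too stays open. The 336 Zfp genes, seen before and therefore left out, had -0.33.

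Markers of other cell types stood higher with JP2NT, in 61 marker genes of fibroblasts, endothelium, smooth muscle and macrophages. A larger share of such cells in the JP2NT cultures may account for it: the brighter markers had a level-adjusted median of 0.54 and the dimmer ones 0.21, and the brighter ones were higher within replicates 1 (0.32) and 2 (0.82), although the macrophage genes Csf1r (-2.03) and Cd68 (-0.69) went the other way. Dim genes raised by the normalization stay open: against genes of like level the median of all markers was 0.36, but 0.09 within replicate 1 and 0.61 within replicate 2. A response of the other cells, or of the cardiomyocytes, to JP2NT was not tested.

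A control probe set for the B1 repeat, a short interspersed element of the mouse genome, read 14.01 ± 0.16 with empty virus, 14.35 ± 0.06 with JP2NT and 13.36 ± 0.38 with JP2 (log2, mean ± SD, n = 2 each), so that it was 0.33 above the control samples with JP2NT, in probe sets outside the comparisons. Among 9160 probe sets with no listed gene, which no comparison used, 100 were called in JP2NT against empty virus, 48 higher and 52 lower, and 192 higher and 187 lower with the replicate block. In JP2NT against JP2 limma called 23, and in JP2 against empty virus 0, or 1 higher and 10 lower with the block.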

How the results depend on the processing

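The block combined with quantile normalization or with an estimated correlation was chosen after seeing the data; the other alternatives were planned. With 2 arrays per group, leaving out an array leaves a lone array that is assumed to vary like the other groups. Where no cause is named, the cause was not tested. No detection calls were used, so what signal over background limits was not tested beyond leaving out dim genes.

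Genes called in JP2NT against empty virus numbered 548. They were 338 with the mean of probe sets, 72 with quantile normalization, 361 with median centring and 255 with only the arrays of the 2 groups, where fewer arrays estimate the spread. Leaving out each array gave 0 to 255, and every array moved the count: 1 without empty virus replicate 1, 255 without JP2 replicate 1 or 2, and 0 without each of the other 3. The other alternatives without the replicate block gave 597 to 727. In JP2NT against JP2 the 237 genes became 128 with quantile normalization, 0 with only the arrays of the 2 groups and 49 when all probe sets were tested; leaving out each array gave 0 to 65, with 65 without JP2 replicate 1 and 0 without each of the other 5. The other alternatives without the replicate block gave 160 to 327. In JP2 against empty virus 0 genes were called under each of the 15 alternatives run. The self-test recovered 76.2% of simulated 4-fold and 1.6% of 2-fold changes, with 200 changed genes. Recovery with fewer changed genes was not tested. The delivered Jph2, 3.57-fold higher on its dimmer probe set, missed the threshold over all probe sets (limma adjusted p = 0.618). The 0 calls therefore do not show that JP2 left gene expression unchanged.

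With the replicate number as a block, 2940 genes passed in JP2NT against empty virus and 2547 in JP2NT against JP2, and with the block and quantile normalization 2764 (55.5% lower, against 92.9% of the 548) and 2427 (53.3% lower, against 88.6% of the 237). The block called 15 and 14 lists in these comparisons, and with quantile normalization 15 in the first. In JP2 against empty virus it changed no call of a gene or list, while the block with quantile normalization called 6 lists. The block with an estimated correlation called 0 lists in each comparison.

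Lists called were 8, 2 and 9 in the order JP2NT against empty virus, JP2 against empty virus and JP2NT against JP2. An estimated correlation called 0 in each. Fry, which tests whether a list moves one way and not against other genes, called 1, 0 and 2: erythroid markers in JP2NT against empty virus, which are not among the 8, and erythroid markers and immediate early genes in JP2NT against JP2, of which the latter are among the 9. Only 4 of the 8 erythroid markers were measured, at a median level of 5.59, below the median of every array. After quantile normalization their median against empty virus was 0.20 (camera adjusted p = 0.258). The fit on only the arrays of the 2 groups called 13 in JP2NT against empty virus, and median centring 1 in JP2 against empty virus. Leaving out each array gave 8 to 14, 2 to 11 and 10 to 13 lists. In JP2NT against empty virus the counts past 1.5 times were 14 without JP2NT replicate 1 and 13 without JP2 replicate 1 or 2; in JP2 against empty virus they were 6 and 7 without empty virus replicate 1 and 2 and 11 without JP2 replicate 1.

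The correlation of the JP2NT and JP2 changes, 0.391, was 0.15 and 0.0814 with different empty virus arrays, which removes the shared controls but also brings the difference between replicate numbers into both changes with opposite sign, 0.327 with quantile normalization, 0.311 with dim genes left out and 0.311 to 0.566 leaving out each array. Jph2 was not among the genes followed through the alternatives. Its brighter probe set differed by 0.038 with JP2NT, from arrays at 11.84 and 10.52 with empty virus and 11.70 and 10.74 with JP2NT. Leaving out an array can therefore turn its sign. Of the genes followed, 5 values reversed, each of a gene not called. In JP2NT against empty virus Atp2a2 was -0.16 with the mean of probe sets, and Mef2c was 0.10 with quantile normalization and with the block and quantile normalization. Leaving out each array gave -0.33 to 0.10 for Mef2c, above 0 without JP2NT replicate 1, and -0.058 to 0.81 for Col1a1, below 0 without JP2NT replicate 2. Of 599 values of 40 called genes in that comparison 328 kept the call and 271 lost it, and of 465 values of 31 genes in JP2NT against JP2 222 kept it and 243 lost it, with 0 reversed in either.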

Other observations

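The lists in this part were written after the data were seen and adjusted over 5 lists, and except for the Zfp family they leave out members seen before; the tests of ribosome biogenesis and proteasome genes had their outcome bounds set before their results were seen.

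Genes of the zinc finger Zfp family, 336 in number and mostly DNA-binding regulators, were listed because their median had been seen below 0 with JP2NT, so no test of the family is given. Against empty virus the median was -0.33 (-0.27 within replicate 1 and -0.37 within replicate 2, -0.28 after quantile normalization), with 31 lower and 0 higher over all genes and 114 lower and 5 higher with the replicate block. Against JP2 the median was -0.20, with 14 lower. In JP2 against empty virus it was -0.06. Circadian clock genes, 16 in number, had a median of 0.26 in JP2 against empty virus (0.091 and 0.46 within replicates 1 and 2, adjusted p = 0.0212, and 0.419 with an estimated correlation) and -0.25 in JP2NT against JP2 (-0.22 and -0.46, adjusted p = 0.000801, and 0.364 with an estimated correlation). In JP2NT against empty virus the clock median was -0.13 (camera adjusted p = 0.125), and 0.00075 against genes of like level. The difference from JP2 thus includes the rise with JP2. Lysosome genes, 19 in number, had a median of -0.26 in JP2 against empty virus (-0.12 and -0.33 within replicates 1 and 2, adjusted p = 0.004, and 0.322 with an estimated correlation). That median was smaller in size after quantile normalization (-0.14, camera adjusted p = 0.0311) and against genes of like level (-0.16). With JP2NT the lysosome median was -0.058 against empty virus and 0.17 against JP2 (camera adjusted p = 0.489 and 0.201).

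Myc was among the genes lower with JP2NT, and as a hypothesis ribosome biogenesis genes, many of them known MYC targets, may be lower with it. Over 36 such genes the median in JP2NT against empty virus was -0.43 (-0.32 within replicate 1 and -0.54 within replicate 2, -0.35 after quantile normalization; adjusted p = 1.95e-08, and adjusted p = 0.124 with an estimated correlation), with 1 lower over all genes, Nolc1 (-1.82, SE 0.23, adjusted p = 0.0278), and 10 with the replicate block. Against JP2 it was -0.36 (adjusted p = 6.01e-06, and 0.199 with an estimated correlation). Set against genes of like level, the median against empty virus was -0.36. In JP2 against empty virus the list's median was also below 0 (-0.13, adjusted p = 0.0482, and 0.419 with an estimated correlation), while Myc differed by 0.88 there (adjusted p = 0.557), which goes against the link; after quantile normalization that median was -0.044 (adjusted p = 0.877). No test links these genes to Myc in these cells.

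Psmb3 was among the genes higher in JP2NT against JP2. As a hypothesis proteasome genes were tested as a group, and over 30 other proteasome genes the median was 0.048, under the bound of 0.1 set against it (adjusted p = 0.565).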
